A study of Rattus norvegicus with 8 samples.

How the data were processed

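RNA was sequenced from 8 subcutaneous tumours grown in NOD-scid mice from ELT3-V3 cells, a rat leiomyoma line. Per the labels' protocols, RNA was extracted with TRIzol and libraries followed the Illumina TruSeq protocol. The authors deposited a single table of TPM values (transcript abundance scaled to a fixed sum) for 23918 Ensembl rat gene IDs, with a column for each tumour that sums to 1000000. The submitters' processing notes name STAR 2.4.0f1, SAMtools 0.1.18, bedtools, DESeq2 and the rat build rn6, without saying what each was used for. The tool that computed TPM, the annotation release, any filter on genes and any removal of mouse host reads are not given in the sources used here.

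TPM divides each gene's reads by its length and scales every library to the same sum, so the values keep no sequencing depth. The depth of each library was therefore unknown, and no counting interval or detection limit was computed. A gene that takes a large share of 1 library lowers the TPM of all others in it. The 100 most abundant genes held between 32.0% and 36.7% of the TPM of a library. Mouse transcripts that align to the rat genome would be included in the values of a xenograft, and their share was not measured here.

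The group of each tumour came from its title, and all 8 columns matched a title. There were 4 groups of 2 tumours, which are vehicle control, rapamycin, rapamycin with clorgyline, and rapamycin with rasagiline. Replicate numbers only name the tumours and pair none across groups. No library held the same values as another. The labels speak of 8 tumours but do not say that each came from its own mouse, so the p-values measure the spread between these tumours.

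Genes with a TPM of at least 1 in at least 2 of the 8 libraries were tested, which left 13686. Values were transformed to log2(TPM + 1). Fold changes are on this scale, which understates the change of genes with low TPM. limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 8 libraries together, with 4 residual degrees of freedom. Variances were moderated with an intensity trend (median prior degrees of freedom 3.37). Each of 7 comparisons was tested two-sided with Benjamini-Hochberg adjustment over the genes tested, and a gene rose or fell where its adjusted p was below 0.05. The comparisons were each rapamycin-containing group against control, the mean of the 3 such groups against control, each combination against rapamycin, and the combinations against each other. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

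The fit was tested on simulated data with 200 changed genes among 13686, in 20 runs. For rapamycin against control it recovered 34.2% of genes changed by a log2 fold of 1, 92.4% at 2, 97.6% at 3 and 99.5% at 4, and 6.55% of calls were false. For the mean of the 3 groups against control it recovered 55.3% at a log2 fold of 1 and 95.4% at 2, with 5.89% of calls false. These simulations gave every group the same spread. The changed genes were drawn only from those with a mean log2(TPM + 1) above 2, so recovery of weaker genes was not tested.

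Gene symbols could not be assigned. The deposited table holds IDs alone, and in the reference table used here (assembly GRCr8, 47357 genes) no entry carried an Ensembl ID, so 0 of the 23918 IDs were matched. Before the data were examined, 33 gene lists had been fixed for pathways and for other cell types that a xenograft can hold. None of these lists could be tested, because their members are symbols. The rule fixed for named genes took, per comparison, the 10 largest changes in each direction among genes with a symbol, an adjusted p below 0.05, no overlap between the groups' libraries and a mean of at least 5 TPM in the higher group, together with genes fixed by symbol. It could not be applied for the same reason. In its place 2 IDs that rose and 2 that fell are named. They were chosen after their values were seen, so their sizes are those of extreme genes.

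Alternatives were another pseudocount (0.1 or 5 TPM), no filter other than a value above 0, a filter of 5 TPM, quantile normalization, median rescaling, variance moderation without a trend, a fit of only the groups compared, and leaving out each library in turn. When a library was left out, the lone tumour of its group was assumed to vary like the other groups. Comparisons that use the same reference libraries share their chance values. Unchanged groups against shared libraries were therefore simulated in 100 draws, in 50 draws for called sets of genes and in 20 for calls against a single rapamycin tumour, and covariances were computed from library pairs with none in common.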

Results

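Gene expression was measured by RNA sequencing in 8 tumours formed by ELT3-V3 cells under the skin of female NOD-scid mice, which were 6 weeks old. ELT3 cells come from a rat uterine leiomyoma that lacks the tumour suppressor tuberin. They serve as a model of lymphangioleiomyomatosis (LAM), a lung disease in which the same pathway is unrestrained. Mice were assigned at random when tumours measured 150 to 200 mm3. There were 2 tumours in each of 4 groups. These received vehicle, rapamycin at 0.25 mg/kg per day, rapamycin with clorgyline at 10 mg/kg per day, or rapamycin with rasagiline at 1 mg/kg per day. Rapamycin inhibits the kinase complex mTORC1. Clorgyline and rasagiline are both propargylamines that inhibit monoamine oxidase irreversibly, with selectivity for the A form and the B form respectively. The series asked whether adding either inhibitor to rapamycin is of benefit in this model. The labels do not repeat the rapamycin dose for the combinations. The deposited values are TPM for genes known by Ensembl ID only, and sequencing depth was unknown.

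Between 17001 and 18012 of the 23918 genes listed had a value above 0 in a library, and between 12317 and 13270 reached 1 TPM. Across the 13686 genes tested, which are not independent replicates, the tumours of a group correlated at r = 0.982 for control, 0.947 for rapamycin, 0.974 for rapamycin with clorgyline and 0.972 for rapamycin with rasagiline. The variance between replicates, averaged over genes on the log2 scale, was 0.093, 0.275, 0.133 and 0.124 in the same order. Rapamycin replicate 2 differed from the other libraries by a mean of 0.783 (root mean square, log2), against 0.586 to 0.663 for each other library. It correlated at r = 0.956 with rasagiline combination replicate 2, above the 0.947 with its own group's replicate 1.

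**Figure D1:**
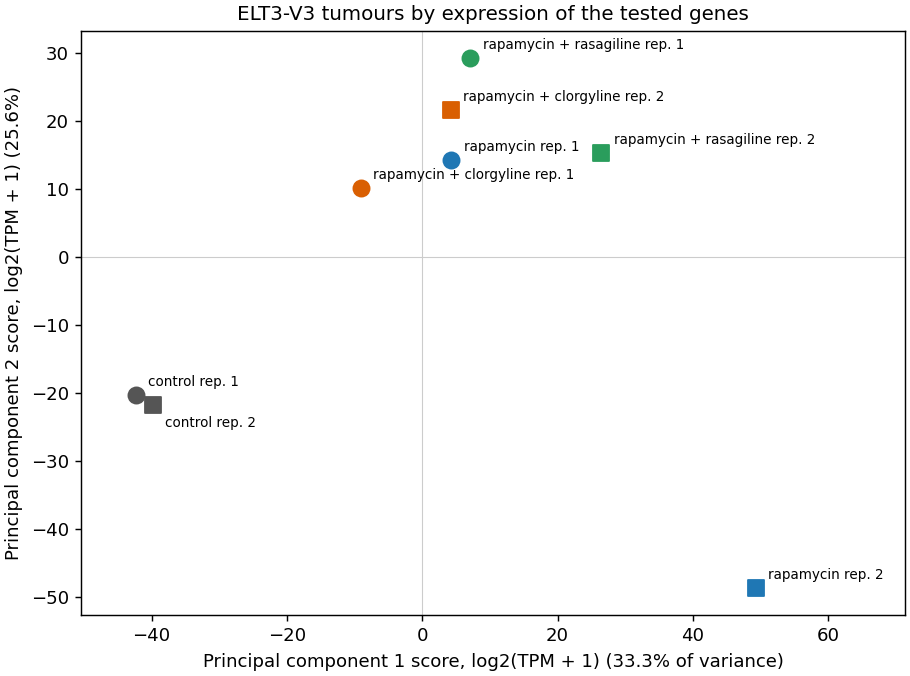
Principal component scores of the 8 tumours from log2(TPM + 1) of the genes tested, with component 1 (33.3% of the variance) on the horizontal axis and component 2 (25.6%) on the vertical axis; colours mark groups, circles replicate 1 and squares replicate 2. The controls lie at -42.4 and -39.8 on component 1, and rapamycin replicate 2 lies apart from the other treated tumours at 49.3 on component 1 and -48.7 on component 2.

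The comparison of rapamycin with control asks how tumours given rapamycin alone differed from those given vehicle. 32 genes rose and 56 fell after rapamycin, and 36 rose and 98 fell after median rescaling (34 and 82 after quantile normalization). The median log2 fold change was 1.94 among the genes that rose and -2.09 among those that fell. ENSRNOG00000008816 fell from 2001 ± 112 TPM (SD, n = 2) in controls to 468 ± 7.37 TPM (SD, n = 2), which is 4.27-fold lower (log2 fold change -2.09, SE 0.161; limma, Benjamini-Hochberg adjusted p = 0.011). ENSRNOG00000048953 fell from 18.8 ± 8.18 TPM to 0.600 ± 0.161 TPM (SD, n = 2 each), with a log2 fold change of -3.57, SE 0.414 and limma adjusted p = 0.0339. ENSRNOG00000052713 was listed at 0 in both controls and at 16.3 and 20.03 TPM in the rapamycin tumours (limma adjusted p = 0.00269). In all 88 genes the values of the rapamycin tumours did not overlap those of the controls. This follows largely from their selection on these same tumours and is not separate support. At an unadjusted p below 0.05 there were 2554 genes in the limma fit, against 684 expected by chance.

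The number of genes called in this comparison depended on single tumours. It was 0 without either control, 1327 without rapamycin replicate 1, 11 without either clorgyline combination tumour, and 16 or 17 without rasagiline combination replicate 1 or 2. Without rapamycin replicate 2 it was 62, of which 34 rose and 28 fell, so that more genes rose than fell, and 26 of the 62 were among the 88. The limma adjusted p of ENSRNOG00000048953 ranged from 0.0132 to 0.246 when single libraries were left out. With all libraries kept, its call was lost at a pseudocount of 0.1 TPM (adjusted p = 0.0634), with no filter (0.0775), with array weights (0.074) and with only these 2 groups fitted (0.103). Its log2 fold change was -4.70 at a pseudocount of 0.1 TPM and -2.04 at 5 TPM. ENSRNOG00000008816 had a limma adjusted p of 0.0763 with only these 2 groups fitted. Without control replicate 1 or 2 its log2 fold change was -2.04 or -2.15, and that of ENSRNOG00000048953 was -3.13 or -4.00. That of ENSRNOG00000052713 was 4.25 without either control. Leaving out a control also removes the least variable group's part of the shared spread. The loss of calls alone therefore does not show that the changes rest on a single control.

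Rapamycin with clorgyline against control asks what the clorgyline combination did relative to untreated tumours. 1 gene rose and 1 fell. ENSRNOG00000052713 stood at 15.4 and 14.5 TPM, against 0 listed in both controls (limma adjusted p = 0.00631). ENSRNOG00000008816 fell 5.27-fold, from 2001 ± 112 to 382 ± 67.1 TPM (SD, n = 2 each; log2 fold change -2.40, SE 0.161; limma adjusted p = 0.00631). ENSRNOG00000048953 stood at 1.65 ± 0.880 TPM (SD, n = 2), and its log2 difference of -2.88 from control did not pass the limma test (adjusted p = 0.0967). The same difference passed when only these 2 groups were fitted (limma adjusted p = 0.0279). At an unadjusted p below 0.05 there were 1851 genes, against 684 expected by chance. The fit shares its spread with the rapamycin group. The count was 138 without rapamycin replicate 1, 140 without rapamycin replicate 2 and 204 when only these 2 groups were fitted, and 0 without either control or either clorgyline combination tumour.

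Rapamycin with rasagiline against control asks what the rasagiline combination did relative to untreated tumours. 146 genes rose and 69 fell, with median log2 fold changes of 1.87 and -1.39. ENSRNOG00000008816 fell 5.89-fold to 339 ± 3.03 TPM (SD, n = 2; log2 fold change -2.56, SE 0.161; limma adjusted p = 0.00467), and ENSRNOG00000048953 fell to 0.437 ± 0.50 TPM (SD, n = 2; log2 fold change -3.76, SE 0.414; limma adjusted p = 0.0219). ENSRNOG00000052713 stood at 12.1 and 7.70 TPM (limma adjusted p = 0.00516). ENSRNOG00000016837 rose from 1.66 ± 0.395 to 37.4 ± 0.501 TPM (SD, n = 2 each; log2 fold change 3.86, SE 0.261; limma adjusted p = 0.00467). Its log2 fold change was 4.43 at a pseudocount of 0.1 TPM and 2.67 at 5 TPM, and that of ENSRNOG00000048953 was -5.47 and -2.09, with both genes still called.

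The share of these calls that rose was 67.9%. It was 49.6% (115 rose, 117 fell) after quantile normalization and 45.8% (115 rose, 136 fell) after median rescaling. As deposited, the median log2 difference of all tested genes in this comparison was 0.149, which moved to -0.010 and 0.003 under these scalings. The count was 0 without either control or without rasagiline combination replicate 1, and 6 without its replicate 2. It was 13 or 16 without clorgyline combination replicate 1 or 2, and 975 or 983 without rapamycin replicate 1 or 2.

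The mean of the 3 rapamycin-containing groups was set against control, which averages the groups and can also call a gene that changed in a single group. 171 genes rose and 163 fell, with median log2 fold changes of 1.201 and -1.12. In 168 and 160 of these the 6 treated tumours did not overlap the 2 controls. The genes were selected on these same tumours, so the separation is not independent support. ENSRNOG00000008816 lay between 334 and 473 TPM in the 6 treated tumours and at 1922 and 2080 TPM in the controls (log2 fold change -2.35, SE 0.132; limma adjusted p = 0.00169). ENSRNOG00000048953 lay between 0.083 and 2.27 TPM, against 13.0 and 24.6 TPM (log2 fold change -3.40, SE 0.338; limma adjusted p = 0.0221). ENSRNOG00000052713 lay between 7.70 and 20.03 TPM, and was listed at 0 in both controls (limma adjusted p = 0.00169). ENSRNOG00000016837 was also called (log2 fold change 1.51, limma adjusted p = 0.0276), although against control it passed the test with rasagiline but not with rapamycin alone (limma adjusted p = 0.503) or clorgyline (limma adjusted p = 0.64). With no filter on low values, the adjusted p for the mean was 0.0696 for ENSRNOG00000016837 and 0.0501 for ENSRNOG00000048953.

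The share of calls that rose was 51.2%, and was 37.8% after quantile normalization and 34.5% after median rescaling. It was 58.2% at a pseudocount of 0.1 TPM, 59.8% with array weights and 61.9% without rapamycin replicate 2, so the data did not fix which direction held more genes. The median log2 difference of all tested genes was 0.105 as deposited and 0.004 and 0.010 under these scalings. The count of 334 became 0 without either control, 1317 or 1044 without rapamycin replicate 1 or 2, 37 or 7 without clorgyline combination replicate 1 or 2, and 74 or 56 without rasagiline combination replicate 1 or 2.

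**Figure D2:**
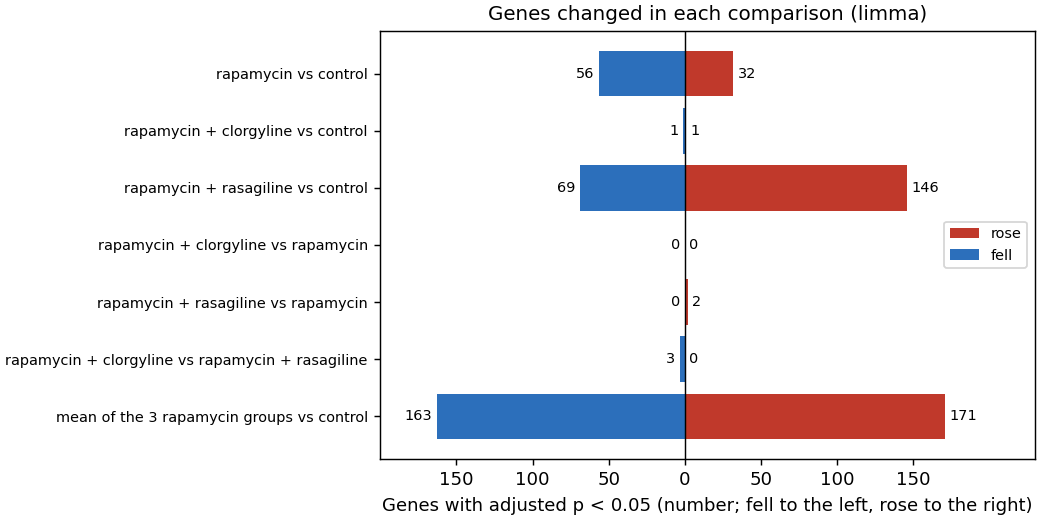
Number of genes that rose (right, red) or fell (left, blue) at a limma adjusted p below 0.05 in each of the 7 comparisons, out of 13686 tested. Comparisons against control gave between 2 and 334 genes, and comparisons among the rapamycin-containing groups gave between 0 and 3.

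Genes called after rapamycin alone were followed in the combinations. Of the 32 that rose, 31 were also higher than control with clorgyline (median log2 difference 1.32) and 31 with rasagiline (median 1.65). Of the 56 that fell, 54 were also lower with clorgyline (median -1.07) and 56 with rasagiline (median -1.51). These comparisons share their controls. In unchanged groups simulated against shared controls, a mean of 89.2% to 90.6% of the genes in equally sized sets kept the sign. Rapamycin and the rasagiline combination shared 22 genes that rose and 32 that fell. Independent lists would share 0.341 and 0.282, and simulated unchanged groups shared 12.5 and 13.1. The first of these values leaves out the shared controls and the simulation leaves out any effect. The simulations of called genes also gave every group the same spread. The controls varied least (0.093, against 0.124 to 0.275 in the other groups). The simulated shares and overlaps may therefore overstate what shared controls alone would give, and no version with each group's own spread was run. With either control alone both comparisons called 0 genes, so no overlap could be counted with separate controls, and part of the overlap may come from the shared controls.

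Across genes, the log2 changes against control of rapamycin and of the clorgyline combination correlated at r = 0.636, against 0.50 in simulated unchanged groups. The correlation was 0.736 for rapamycin and the rasagiline combination (simulated 0.499) and 0.765 for both combinations (simulated 0.50). The covariances were 0.204, 0.274 and 0.245, each against 0.078 simulated. With each group's own spread, the simulated correlations were 0.320, 0.329 and 0.417 and each simulated covariance was 0.046. When no library was used on both sides, the mean covariances were 0.159, 0.228 and 0.199.

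Each combination was then compared with rapamycin alone, which asks what the second drug added. With clorgyline, 0 genes passed the limma test (smallest adjusted p = 0.11), and 1042 had an unadjusted p below 0.05 against 684 expected by chance. Replicate differences from rapamycin that shared no library had a covariance across genes of 0.057 in 1 pairing and 0.044 in the other (r = 0.144 and 0.108). The absence of calls therefore does not show that clorgyline added nothing. ENSRNOG00000016837 stood at 2.30 ± 0.337 TPM with clorgyline and 2.42 ± 0.894 TPM with rapamycin alone (SD, n = 2 each), a log2 difference of -0.03 with a 95% interval from -0.64 to 0.58. For ENSRNOG00000008816 the interval ran from -0.68 to 0.08 (log2). The interval lay within ± 1 log2 unit for 64.0% of all genes, so a change beyond that size could not be excluded for the remainder. These intervals use the spread shared by all groups. The rapamycin tumours varied most (variance 0.275, against 0.093 to 0.133 in the other groups), so intervals against rapamycin may be too narrow. Without rapamycin replicate 1 the count was 441, without rapamycin replicate 2 it was 2, and without rasagiline combination replicate 2 it was 3.

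With rasagiline, 2 genes rose relative to rapamycin alone and 0 fell. ENSRNOG00000016837 rose from 2.42 ± 0.894 to 37.4 ± 0.501 TPM (SD, n = 2 each; log2 fold change 3.52, 95% interval 2.90 to 4.13; limma adjusted p = 0.0254). The log2 fold change was 3.94 at a pseudocount of 0.1 TPM and 2.52 at 5 TPM. The limma adjusted p was 0.0815 with no filter and 0.0561 after quantile normalization, and ranged from 0.00962 to 0.259 when single libraries were left out. The other gene rose 5.07-fold, from 22.04 ± 3.04 to 116 ± 15.9 TPM (SD, n = 2 each; limma adjusted p = 0.0366). At an unadjusted p below 0.05 there were 795 genes, against 684 expected by chance. The count was 405 without rapamycin replicate 1, 4 without rapamycin replicate 2 and 0 without any single tumour of the other groups. It was also 0 when only these 2 groups were fitted, where ENSRNOG00000016837 kept its log2 fold change of 3.52 with a limma adjusted p of 0.612. Across all genes, replicate differences from rapamycin that shared no library had covariances of 0.060 and -0.055 (r = 0.191 and -0.131), which differ in sign.

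The combinations were compared with each other to set clorgyline against rasagiline, which differ in structure as well as in dose (10 and 1 mg/kg per day), so the doses were not matched. 3 genes were lower with clorgyline and 0 were higher. ENSRNOG00000016837 was lower, at 2.30 ± 0.337 against 37.4 ± 0.501 TPM (SD, n = 2 each; log2 fold change -3.55, SE 0.261; limma adjusted p = 0.0239). The log2 fold change was -3.97 at a pseudocount of 0.1 TPM and -2.54 at 5 TPM, and the limma adjusted p was 0.071 with no filter. Another gene stood at 20.7 ± 3.67 against 116 ± 15.9 TPM (limma adjusted p = 0.028), and the remaining gene at 0.256 ± 0.0204 against 21.7 ± 3.26 TPM (limma adjusted p = 0.0409; SD, n = 2 each). At an unadjusted p below 0.05 there were 629 genes, against 684 expected by chance. The 95% interval of the difference lay within ± 1 log2 unit for 67.7% of genes. The count was 0 without any single control or combination tumour, and 4 without either rapamycin tumour.

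**Figure D3:**
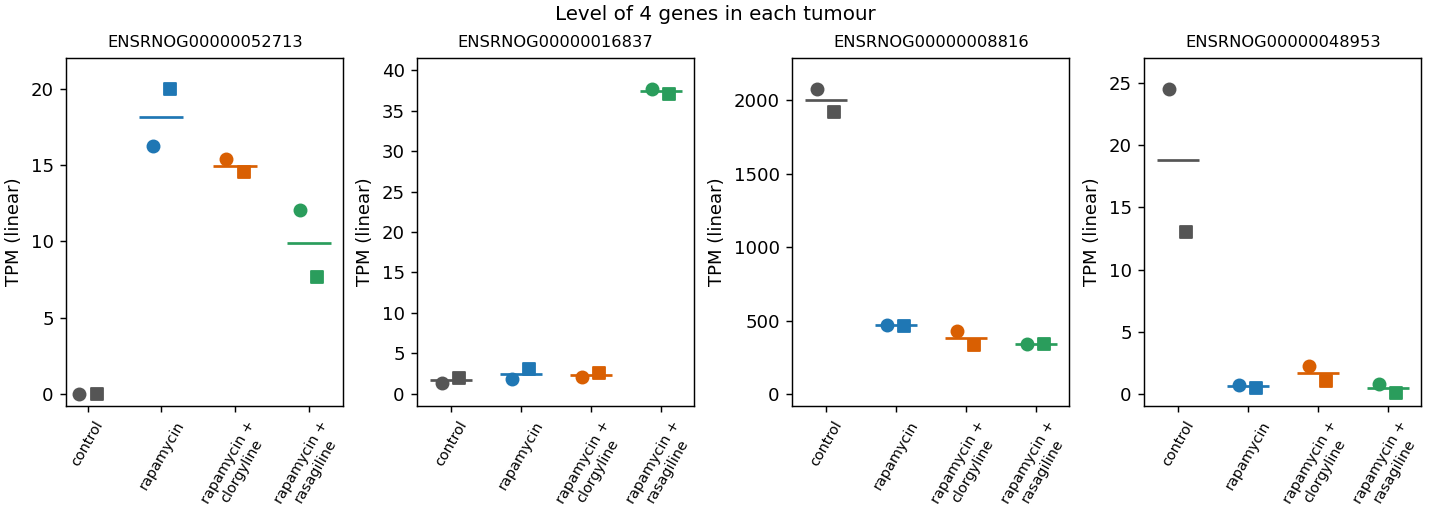
TPM of 4 genes in each tumour on linear axes, with circles for replicate 1, squares for replicate 2 and a line at the group mean where it is above 0. ENSRNOG00000052713 is listed at 0 in both controls and reaches 7.70 to 20.03 TPM in treated tumours, ENSRNOG00000016837 reaches 37.0 and 37.7 TPM with rasagiline and at most 3.05 TPM elsewhere, and the other 2 genes are lower in all 6 treated tumours.

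The log2 changes that clorgyline and rasagiline added to rapamycin correlated across genes at r = 0.644. Both differences use the same rapamycin tumours. Simulated unchanged groups gave 0.498 with a spread common to all groups and 0.681 with each group's own spread. The covariance was 0.140, against 0.078 and 0.138 in the same simulations. When the differences were taken from different rapamycin tumours, r ranged from -0.151 to 0.142 over 8 choices of libraries and the mean covariance was 0.009.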

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

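Array weights, the fit with 2 groups only and the covariances from separate libraries were chosen after seeing the data, and the other alternatives before the data were examined. Leaving out single libraries gave 0 to 1327 genes for rapamycin against control, 0 to 140 for the clorgyline combination against control, 0 to 983 for the rasagiline combination against control, and 0 to 1317 for the mean of the 3 groups. The ranges were 0 to 441 and 0 to 405 for the clorgyline and rasagiline combinations against rapamycin, and 0 to 4 between the combinations. For r between the changes added by each drug the range was 0.518 to 0.843, the highest without rapamycin replicate 1. Leaving out either control gave 0 genes in all 7 comparisons. Each omission removes a group's part of the shared spread, largest for rapamycin and smallest for control.

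Against control, no filter gave 6 genes for rapamycin, 4 for the clorgyline combination, 67 for the rasagiline combination and 22 for the mean. Without a variance trend there were 50, 3, 104 and 137 genes, and with array weights 4, 5, 1409 and 1083. The array weights came out equal for both tumours of a group, so they weighted groups. Fitting only the groups compared gave 4, 204 and 916 genes for the single groups, and 2 groups of 6 and 2 tumours gave 379 for the mean. Median rescaling gave 134 genes for rapamycin, and a pseudocount of 5 TPM gave 7 for the clorgyline combination.

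For the clorgyline combination against rapamycin, a pseudocount of 0.1 TPM gave 1 gene. For the rasagiline combination against rapamycin, pseudocounts of 0.1 and 5 TPM gave 5 and 6 genes, no filter 0, quantile normalization 1, no trend 1, array weights 1 and only the groups compared 0. Between the combinations a pseudocount of 5 TPM gave 6 genes and no filter 0. With no filter the test covered 20134 genes; otherwise the cause was not tested.

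Of 247 values of the 4 named genes under settings that kept all libraries, 235 kept their direction and side of the threshold, 11 lost the call, 1 gained it and 0 changed sign. With a library left out, 57 of 224 lost it, 2 gained it and 4 changed sign, all below the threshold for a call. Both totals include values not called in the main fit, which could not lose a call. The share lost among called values was therefore larger than these totals imply. The log2 difference of ENSRNOG00000016837 between the clorgyline combination and rapamycin (-0.03) ranged from -0.30 to 0.24, with 0.07 without clorgyline combination replicate 1 and the highest without rapamycin replicate 2. That of ENSRNOG00000008816 between the combinations (0.16) ranged from -0.019, without clorgyline combination replicate 1, to 0.34. That of ENSRNOG00000048953 between the rasagiline combination and rapamycin (-0.20) ranged from -0.56 to 0.17, the latter without rasagiline combination replicate 2. The alternatives fixed for gene lists were not run, since no ID had a symbol. No paired analysis was run because the labels do not say what the letter and digit in each title mark, though some recur across groups. Deviations from the group mean correlated at -0.015 to 0.170 between tumours sharing a letter and at -0.170 to 0.319 between those sharing a digit. The highest was between rapamycin replicate 2 and rasagiline combination replicate 2, and this check was added after seeing the data. In groups of 2 the deviations mirror each other, so 0.170 and -0.170 are the same value with opposite signs. The check therefore cannot separate letter from digit. Depth was unknown, so its effect on genes with low TPM could not be measured.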

Other observations

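The tests of splits, of rapamycin replicate 2, of the ratios between rapamycin tumours with their simulation, and of the slopes were chosen after fits and values per library had been seen. The most abundant gene of the controls stood at 31726 and 35508 TPM there, at 15605 and 3620 TPM with rapamycin, at 29462 and 9698 TPM with clorgyline added, and at 14152 and 7681 TPM with rasagiline added. It passed the limma test in none of the 7 comparisons (adjusted p from 0.187 to 0.997).

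A fit of the 6 rapamycin-treated tumours against the 2 controls called 379 genes. Each other choice of 2 of the 8 tumours called at most 8, so 1 of the 28 splits, the real one, gave as many. Ranking first is the most that 28 splits can show, and the test was chosen after fits had been seen. It therefore does not exclude chance, and it cannot tell treatment from anything else that the 2 controls share. Which of the genes respond to rapamycin itself was not tested apart from the vehicle or the growth of the tumours.

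Rapamycin replicate 2 stood apart from the other 7 libraries, with 34 genes at 10 TPM or more in all others and over 4-fold lower here, against at most 1 such gene in another library. A wrongly labelled untreated tumour was argued against, because over 1044 genes called without this library its median position was 0.912, where 0 is the controls and 1 the other treated tumours. Tissue that the other tumours lacked was argued against, since 1 gene reached 10 TPM here and stayed below 1 TPM elsewhere, and another library had 2. That test counted only genes gained here, so it does not bear on the 34 lower genes, whose source was not tested. Another 10 TPM criterion, over 4-fold above all other libraries, was met by 10 genes here and by 10 in clorgyline combination replicate 2. A larger share of mouse host tissue present in every tumour stays open, because the marker lists could not be matched to IDs. For lower depth, the SD of this library's deviations over 2922 genes averaging at least 50 TPM was 0.601, against 0.279 to 0.337 in the other treated tumours and 0.483 in control replicate 1, which makes 1.24 times the largest. That ratio exceeded the bound of 1.2 set for the test, but its 95% interval from resampling genes ran from 1.17 to 1.33. The interval was added after the ratio was known. The reference was a control, whose deviation from mostly treated tumours also includes the difference between treated and control tumours. The other treated tumours lack that difference and had lower SDs, but no interval was computed against them. With depth unknown, a contribution from it may remain.

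The number of genes called between a combination and rapamycin depended on which rapamycin tumour was used, with 441 genes for clorgyline and 405 for rasagiline against replicate 2 alone, and 226 on both lists. Their median difference from replicate 1 was 0.076 times that from replicate 2 for clorgyline and 0.151 times for rasagiline, but genes chosen for their difference from replicate 2 tend to a low ratio. In 20 simulated sets with no drug effect and each group's own spread, 365 to 593 and 356 to 527 genes were called, with ratios of 0.033 to 0.170 and 0.012 to 0.140. The share of genes on the same side of replicate 1 was 64.9% and 68.6%, against 52.9% to 61.7% and 51.0% to 58.9% simulated. The simulated spread of the rapamycin group was the observed gap between its 2 tumours, so calls in such number were built in. Both shares on the same side, and the ratio for rasagiline, lay above every simulated set. The ratio for clorgyline lay within the simulated range. An effect of either drug stays open.

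A hypothesis is that clorgyline moves genes changed by rapamycin part of the way back toward control. The rapamycin effect was taken from a single rapamycin tumour against the controls, and the step to the combination from the other rapamycin tumour. The slope of the step on the effect was -0.192 for clorgyline, with negative covariance in 4 of 4 choices of libraries (-0.061 to -0.012). The response may therefore be slightly weaker in the clorgyline combination. The labels do not repeat its rapamycin dose and no group received clorgyline alone, so a lower dose cannot be told apart from an effect of clorgyline. For rasagiline the slope was 0.159, with covariances from -0.010 to 0.108 and 1 of 4 negative, and its direction could not be decided. The 4 choices share libraries and every choice uses rapamycin replicate 2, so they are not independent and no p-value was given.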
